A study of Mus musculus with 24 samples.

How the data were processed

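RNA was sequenced from mouse uterine stromal cells of the strain B6CBAF1/J, cultured for 24 h before harvest. The 24 libraries form 8 groups of 3, and the labels number the members of each group 1 to 3 as biological replicates. Decidual stromal cells (DSC) were purified from implantation sites, and myometrial stromal cells (MSC) from the muscle layer of the uterus. Uterine stromal cells (USC) came from the whole uterus, without decidualization, of non-pregnant mice given progesterone, and their labels carry the same embryonic day as the E7.5 samples. DSC and MSC were taken at E7.5 and E15.5. At E7.5, matched cultures of DSC, MSC and USC received TNF-alpha plus interferon-gamma for the last 6 h, and these groups are called treated below.

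Per the labels' protocols, RNA was extracted with RNeasy columns, poly(A)+ RNA was selected with oligo(dT) beads and strand-specific libraries were made by the dUTP method. Per the submitters' processing notes, bcl2fastq, STAR, Picard, HTSeq and DESeq2 were used with the mm10 and GRCm38 builds. Their versions, parameters, the strand setting of the counting and the gene annotation are not given in the sources used here. The deposited count tables hold whole-number counts of reads per gene symbol, not normalised. One table holds the 18 libraries labelled E7.5 with 41012 genes, and another holds the 12 untreated DSC and MSC libraries of both days with 45076 genes. The untreated E7.5 DSC and MSC libraries stand in both tables, with 38030 symbols in common, so the genes were counted separately for the pair of tables. The authors also deposited a normalised signal for each count table, which equalled the counts divided by 1 size factor per library and served here only as a check. All tests stayed within a table.

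The main test was edgeR's quasi-likelihood F test (R 4.3.3, edgeR 4.0.16, limma 3.58.1) with 1 coefficient per group, all libraries of a table in the fit, TMM scaling and robust dispersion. Genes passed filterByExpr with its minimum count of 10, minimum total of 15 and large group size of 10, which left 15805 and 17423 genes. Adjusted p-values are Benjamini-Hochberg values over all genes tested, and a call needed an adjusted p under 0.05. Levels in CPM use the same scaling, and their errors are SDs over 3 libraries. Log2 differences carry a standard error (SE) derived from the F statistic. A difference between responses (interaction) was tested as a contrast of 4 groups.

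The 26 gene lists, the tests, the named genes and all alternatives except those said to be added later were fixed before the data were examined. Named genes are, per comparison, the 5 largest positive and 5 largest negative log2 fold changes among calls with a mean of at least 5 CPM and groups that did not overlap (no such condition for interactions), leaving out predicted genes. They also include the 2 members of each list with the smallest p and always Cxcl9, Cxcl10, Cxcl11, Ccl5, Pgr, Ezh2 and Acta2; the text names a part of these, picked after the values were seen. The lists were CXCR3 and CCR5 ligand chemokines, other chemokines, antiviral interferon-stimulated genes, interferon-gamma-induced GTPases and regulators, MHC class I, MHC class II, NF-kappaB targets, TNF and interferon-gamma receptors and signalling, decidualization, smooth muscle, fibrillar matrix, TGF-beta and YAP targets, parturition and prostaglandin genes, Polycomb and H3K27 demethylase genes, posterior Hox genes, cell cycle, hypoxia and glycolysis, immediate early and stress genes, and markers of myeloid cells, NK and T cells, endothelium, epithelium, trophoblast, pericytes, mesothelium and red cells. Lists were tested with limma's camera on log2 CPM (prior count of 2, preset correlation of 0.01), with Benjamini-Hochberg adjustment over the lists of a comparison that had at least 3 tested members. Camera with an estimated correlation and fry were run beside it.

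Treated and untreated cultures carry the same replicate numbers. The deviations from the group means correlated at 0.55 to 0.62 between DSC libraries of the same number and at 0.34 to 0.65 for MSC, above the threshold of 0.1 in every pair, so these numbers were read as pairs and a fit with the replicate number as a block stands beside the DSC and MSC results it changes and beside the chemokines in the comparisons with USC. The other comparisons did not meet the rule. Alternatives were RLE scaling, no filter, only the groups compared, DESeq2 1.42.0, the block, and each library left out in turn. The labels give no sequencing batch or date.

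Library totals ran from 10.9 to 30.4 M counts in the E7.5 table and from 10.7 to 33.6 M in the table with both days. Libraries of a group differed by far more than sampling noise, with a chi-square per gene of 3.33 to 43.4 and 9.16 to 164 over genes with a summed count of at least 20. The values of 163 and 164 came only from pairs with E15.5 DSC replicate 2. Where a group had no counts, a fold is a lower bound against 3 counts over the pooled libraries of that group, and such bounds cover counting error only. Gene positions come from GENCODE M21 on GRCm38, in which 89.8% and 92.5% of the symbols of the tables were found; that annotation may differ from the authors'. On simulated counts for DSC treated against untreated (15663 genes), the test recovered 40.9%, 64.2% and 83.3% of genes changed by folds of 1.5, 2 and 4. For the difference between the DSC and MSC responses (15657 genes) it recovered 17.9%, 49.2% and 68.8%, and for E15.5 against E7.5 in DSC (16823 genes) 4.62%, 41.5% and 74.6%. Unchanged genes made up 3.1%, 3.3% and 3.75% of these calls. The simulations changed 199, 196 and 193 of the tested genes, with independent noise and no paired cultures or outlying library. The real comparisons called far more genes, so these shares may not hold for them. Members of the prolactin, Psg, Ceacam, granzyme, H2-Q, histone, Tgtp and alpha-globin families share sequence, so reads could be split among copies and their single values are uncertain. No per-sample column of the tables was left out. H3K27me3 was not measured in this series and histone marks are not analysed here.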

Results

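Stromal cells of the mouse uterus were cultured and their poly(A)+ RNA sequenced in 8 groups of n = 3. At E7.5 these were decidual stromal cells (DSC), myometrial stromal cells (MSC) and whole-uterus stromal cells of progesterone-treated non-pregnant mice (USC), each untreated or treated with TNF-alpha plus interferon-gamma for 6 h. At E15.5 they were untreated DSC and MSC. Library totals in M counts were 10.9 to 18.4 for E7.5 DSC, 14.2 to 22.3 for treated DSC and 16.6 to 30.4 for E7.5 MSC. They were 16.3 to 18.9 for treated MSC, 11.6 to 21.6 for USC and 11.5 to 20.9 for treated USC. They were 25.5 to 29.3 for E15.5 DSC and 26.1 to 33.6 for E15.5 MSC. Levels are mean ± SD CPM, folds are log2 ± SE, and adjusted p-values are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The lists and tests were chosen before the data were examined, as were all alternatives but those named in the closing section as added later.

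In DSC, the cytokines raised the T-cell chemokines Cxcl9 (chromosome 5, 92321347 to 92328079, minus strand) to 176 ± 96.4 from 0.471 ± 0.242 CPM (log2 8.63 ± 0.44, adjusted p = 1.6e-09). Cxcl10 (chromosome 5, 92346638 to 92348889, minus strand) rose to 428 ± 208 from 2.14 ± 1.12 CPM (7.71 ± 0.39). Cxcl11 rose by 9.17 ± 0.77, whereas Ccl5 (chromosome 11, 83525778 to 83530518, minus strand) stood at 0.7 ± 0.661 against 0.134 ± 0.141 CPM (2.54 ± 1.12, adjusted p = 0.21, and 2.37 with adjusted p = 0.0027 when blocked by replicate). The interferon-gamma-induced GTPases Igtp (955 ± 122 against 2.68 ± 0.664 CPM, 8.50 ± 0.18) and Irgm1 (6.22) rose, as did the peptide transporter genes Tap1 (444 ± 22.9 against 14 ± 3.06 CPM) and Tap2 (2.40). Ubd, a ubiquitin-like gene, reached 25.3 ± 9.42 CPM from 0 counts, at least 368-fold. Irg1, which encodes the itaconate-producing enzyme, rose by 9.97 to 52.7 ± 16.1 CPM, the antiviral gene Oasl2 by 5.49 ± 0.21 and Xaf1 by 4.44. The monocyte attractant Ccl2 rose by 6.18 ± 0.46, the neutrophil attractant Cxcl1 by 4.21, the mitochondrial dismutase Sod2 by 2.78 and the prostaglandin E synthase Ptges by 2.18 ± 0.21. The growth factor Tgfb3 (-1.44 ± 0.17), the retinol-esterifying enzyme Lrat (-2.14 ± 0.38), the guanylate cyclase subunit Gucy1a3 (-2.06 ± 0.25), the Polycomb gene Cbx2 (-0.87 ± 0.14) and Fos (-1.01 ± 0.19) fell. MHC class II genes did not pass the test, with Ciita, their master regulator, at 0.69 ± 0.305 against 0.172 ± 0.074 CPM (1.81, adjusted p = 0.1, blocked 1.80, adjusted p = 0.025). Cd74 was at 2.18 (adjusted p = 0.086, blocked 2.17, adjusted p = 0.0047, and 0.0016 without treated DSC replicate 3). The progesterone receptor Pgr (chromosome 9, 8899833 to 8968611, plus strand) was at 1090 ± 85.3 against 1190 ± 131 CPM (-0.13, adjusted p = 0.46). The H3K27 methyltransferase gene Ezh2 (chromosome 6, 47530139 to 47595341, minus strand) was at 17.5 against 20.9 CPM (-0.25, adjusted p = 0.2, blocked -0.26, adjusted p = 0.043).

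Among the gene lists in DSC, 21 of 21 interferon-gamma-induced GTPases and regulators rose (21 adjusted over the list alone, median log2 6.87, camera adjusted p = 4.51e-74). All 20 MHC class I genes rose (20, 2.27, adjusted p = 2.55e-50), with 21 of 23 antiviral genes (22, 3.51, adjusted p = 1.03e-42). Of the NF-kappaB targets 22 of 23 rose (22, 1.85, adjusted p = 6.34e-38). Of the CXCR3 and CCR5 ligand chemokines 3 of 4 rose (4, 8.17, adjusted p = 6.02e-11), and of the other chemokines 8 of 17 (8, 1.98, adjusted p = 1.97e-07). Of 16 receptor and signalling genes 6 rose, among them Ifngr2 (0.96) and Traf2 (0.63). Over the list alone 8 were higher and 1 lower (median 0.27, adjusted p = 5.19e-05, adjusted p = 0.11 with an estimated correlation). No MHC class II gene of 7 was called by edgeR (2 adjusted over the list alone, median 0.18, camera adjusted p = 0.16). Blocking by replicate gave camera calls for decidualization (adjusted p = 0.044 against 0.29), cell cycle (0.0013 against 0.064), immediate early genes (0.025 against 0.16) and endothelium (0.0013 against 0.29). The direction was lower except for immediate early genes. In all, 1343 of 15805 genes passed. Of these, 835 were higher and 508 lower, 552 by at least 2-fold. The blocked fit called 3808, and in it most calls were lower (1595 higher and 2213 lower). With only the groups compared, 672 were called (569 higher and 103 lower). Across all comparisons, camera called 110 of 334 list tests, of which 24 held with an estimated correlation. These were the chemokine, antiviral, GTPase, MHC I and NF-kappaB lists in the 3 cytokine responses, MHC II in MSC and USC, receptors in MSC, the CXCR3 ligands and MHC II in the DSC against MSC difference, and MHC II in DSC against USC.

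In MSC, Cxcl9 rose to 3350 ± 614 from 0.935 ± 0.111 CPM (11.81 ± 0.43, adjusted p = 1.5e-11) and Cxcl10 to 2010 ± 303 from 1.55 ± 0.123 CPM (10.36 ± 0.41). Cxcl11 rose to 443 ± 103 from 0.101 ± 0.0911 CPM (11.99 ± 0.52) and Ccl5 to 188 ± 63.7 from 0.185 ± 0.0645 CPM (adjusted p = 1.2e-09). Ciita rose by 6.29 ± 0.47 and the class II gene H2-Ab1 (chromosome 17, 34257689 to 34269419, plus strand) by 3.68 ± 0.32 to 10.6 ± 4.78 CPM. Igtp (chromosome 11, 58199556 to 58207591, plus strand) rose by 8.33 to 1980 ± 169 CPM, Serpina3f by 11.65 ± 0.30, Tap1 by 4.81, Rtp4 by 6.48, Ccl2 by 5.83 and Sod2 by 3.32. The NF-kappaB inhibitor gene Tnfaip3 (chromosome 10, 19000910 to 19015657, minus strand) rose by 5.41 ± 0.17 to 291 ± 66.7 CPM. Outside these pathways, the activin antagonist Fst (chromosome 13, 114452290 to 114458951, minus strand) rose from 11.7 ± 3.66 to 172 ± 47.3 CPM (3.88 ± 0.26), the gelatinase Mmp9 by 4.66 ± 0.21, the oxygen sensor Egln3 by 2.95 ± 0.33, Ptges by 2.96 and Junb by 1.70 ± 0.11. Gucy1a3 (-3.26 ± 0.27), the natriuretic peptide Nppc (-3.04 ± 0.29), Ngfr (-2.83 ± 0.48) and Ppp1r3c (-3.02) fell. So did Tgfb3 (-1.80), the muscle gene Lmod1 (-1.19), Hoxa10 (-0.59) and Hoxa9 (-0.50). Ezh2 was at 16.1 against 19.5 CPM (-0.28 ± 0.11, adjusted p = 0.061, blocked -0.28, adjusted p = 0.013, and 0.025 without treated MSC replicate 3). All 21 GTPases (median 7.04, camera adjusted p = 5.58e-39), 20 MHC I genes (2.71), 23 NF-kappaB targets (2.80) and 4 CXCR3 and CCR5 ligands (11.09) rose. So did 22 of 23 antiviral genes (23 over the list alone, 5.32), 10 of 17 other chemokines (2.08), 6 of 7 MHC II genes (7, 3.68) and 10 of 16 receptor genes (11, 0.65). Camera also called immediate early genes (9 of 15 rose, median 0.57, adjusted p = 3.92e-04, adjusted p = 0.099 with an estimated correlation). It called glycolysis genes as well (6 of 17, 0.31, adjusted p = 0.0032, adjusted p = 0.69 with an estimated correlation). In total 4761 genes passed edgeR. Of these, 2456 were higher and 2305 lower, 1542 by at least 2-fold. The blocked fit called 7827 (3713 higher and 4114 lower).

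In USC, Cxcl9 rose to 673 ± 71.2 from 0.617 CPM (10.05 ± 0.43, adjusted p = 1.2e-10), Cxcl10 to 1220 ± 112 from 2.89 CPM (8.73 ± 0.39). Cxcl11 rose by 10.99 and Ccl5 to 83.7 ± 23.1 from 0.173 CPM (8.81 ± 0.52). H2-Ab1 rose by 4.48 ± 0.38, Ciita by 3.53 ± 0.40, Igtp by 7.17 and Tap1 by 4.30. Tnfaip3 rose by 4.89, Ccl2 by 5.72, Rtp4 by 6.47 and the membrane-bound chemokine gene Cx3cl1 by 2.57. Fst reached 184 ± 2.29 from 11.3 CPM (4.01 ± 0.26), Mmp9 rose by 4.18, Ptges by 2.62 and the matrix gene Ltbp2 by 2.24. Pgr decreased to 414 ± 35 from 610 ± 28.2 CPM (-0.56 ± 0.09, adjusted p = 3.4e-04). The posterior Hox genes Hoxa10 (-0.73 ± 0.13) and Hoxa11 (-0.55), the collagen genes Col5a1 (-0.89 ± 0.17) and Col6a3 (-0.53) fell. So did Ngfr (-3.19 ± 0.49), Lrrc17 (-3.02), the claudin Cldn15 (-2.67 ± 0.26), Tmem119 (-2.63), Hsd11b2 (-2.54), which inactivates glucocorticoids, and Angpt4 (-2.42). Ezh2 was at 15.6 against 16.1 CPM (-0.05, adjusted p = 0.84). All 21 GTPases (median 7.17, camera adjusted p = 1.17e-56), 20 MHC I genes (2.65), 23 NF-kappaB targets (2.38) and 4 CXCR3 and CCR5 ligands (9.43) rose. They were joined by 21 of 23 antiviral genes (23 over the list alone, 3.48), 6 of 7 MHC II genes (3.53), 9 of 17 other chemokines (10, 2.32) and 8 of 16 receptor genes (0.39, adjusted p = 0.057 with an estimated correlation). Camera also called immediate early genes as higher (5 of 15 rose, 0.28, adjusted p = 2.14e-04, adjusted p = 0.083 with an estimated correlation). So were parturition genes (6 rose and 2 fell of 19, 0.33, adjusted p = 0.025, adjusted p = 0.22 with an estimated correlation). It called fibrillar matrix lower (6 of 27 fell, -0.45, adjusted p = 0.025, adjusted p = 0.65 with an estimated correlation). That value was 0.056 without USC replicate 2 and 0.17 without treated USC replicate 1. The posterior Hox genes were lower (3 of 11 fell, -0.30, adjusted p = 0.031, adjusted p = 0.21 with an estimated correlation, 0.068 without USC replicate 1). In total 2655 genes passed edgeR. Of these, 1211 were higher and 1444 lower, 888 by at least 2-fold. The balance was not stable, with 1364 higher and 1192 lower under RLE scaling, 1185 and 901 without the filter, 1490 and 1383 with DESeq2 and 2104 and 2042 (4146 in all) with only the groups compared. It also turned without USC replicate 1 (964 and 862), USC replicate 2 (931 and 853) and treated USC replicate 3 (999 and 912). The fit blocked by replicate number called 5562 (2258 higher and 3304 lower).

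**Figure D1:**
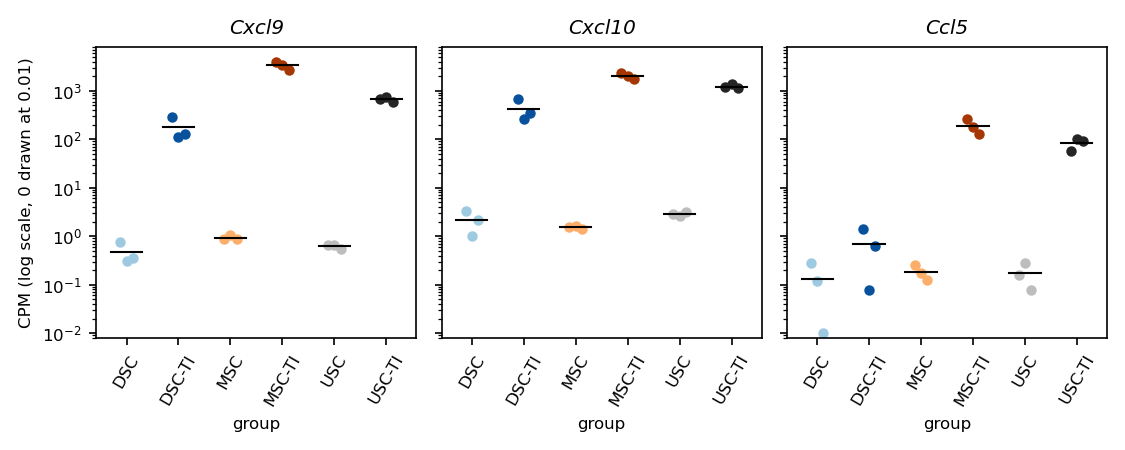
Level in CPM (log axis) of Cxcl9, Cxcl10 and Ccl5 in the 6 E7.5 groups; points are libraries and lines are group means. Ccl5 averaged 0.7 CPM in treated DSC and 188 CPM in treated MSC.

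**Figure D2:**
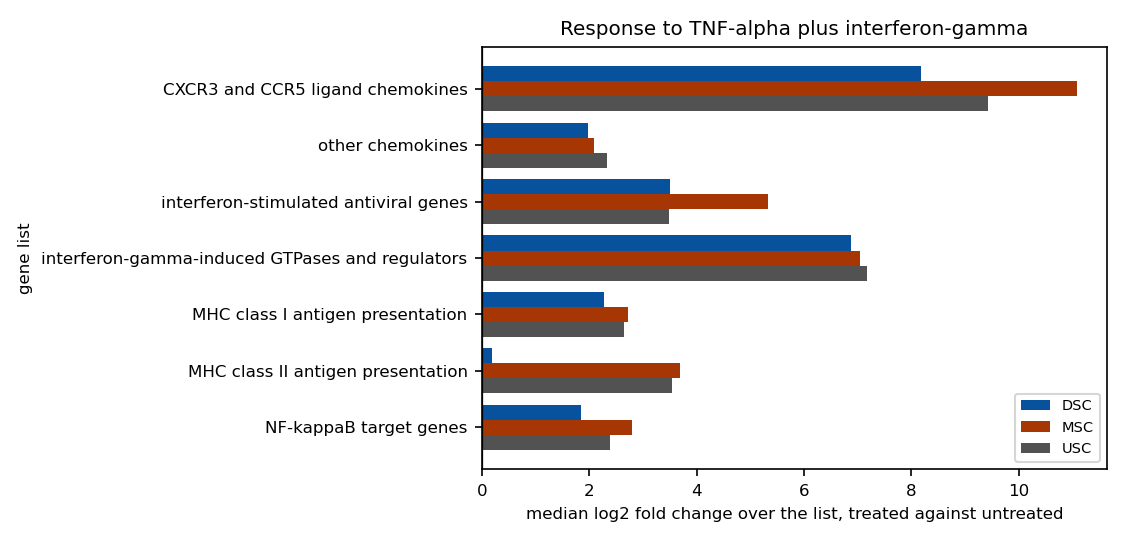
Bars give the median log2 fold change, treated against untreated, of 7 gene lists in DSC, MSC and USC. The medians of MHC II were 0.18, 3.68 and 3.53.

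Genes that rose in both DSC and MSC numbered 751 (130 if independent) and genes that fell in both 317 (74.1). Another 4 plus 15 genes changed in opposite directions. DSC and USC shared 612 (64) and 229 (46.4), and MSC and USC 1128 (188) and 1011 (211). The calls were edgeR's. These pairs of responses had no library in common, but they came from the same fit with the same estimate of each gene's spread. The counts under independence leave this out, so they are no test of the overlap.

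The rise of several immune genes was smaller in DSC than in MSC. The antiviral gene Ifit1 reached 91.7 ± 30.4 from 6.23 CPM in DSC and 586 ± 155 from 3.28 CPM in MSC (difference -3.55 ± 0.54, adjusted p = 1.8e-03). Ifit2 differed by -3.07 and Irf7, which amplifies interferon signalling, by -1.92. The GTPase gene Gbp4 went to 154 ± 45.6 in DSC and to 2240 ± 322 CPM in MSC (-2.53 ± 0.42). Slfn2 was at 153 ± 33 against 47.6 ± 18.9 CPM in DSC and 180 ± 66.5 against 2.39 ± 0.446 CPM in MSC (-4.55 ± 0.44). Fst, already at 301 ± 61 CPM in untreated DSC, differed by -4.48 ± 0.34 (adjusted p = 5.2e-06). Mmp9 (-4.39 ± 0.51), H2-Ab1 (-3.49 ± 0.44), Cx3cl1 (-2.01), H2-T23 (-1.20), and Nfkbia (-1.66 ± 0.13) had smaller log2 changes in DSC. So had Tnfaip3 (-2.01 ± 0.21), Zfp36 (-1.38 ± 0.13), Junb (-1.13), Slc2a1 (-1.46) and Traf2 (-0.69). Cxcl10 differed by -2.64 ± 0.53 (adjusted p = 0.011) and Cxcl9 by -3.19 ± 0.85 (adjusted p = 0.048). Without single libraries the Cxcl9 value was 0.058 to 0.18 in 9 of 12 cases, the exceptions being treated DSC replicates 1 and 2 and treated MSC replicate 3. These fits carried no block, and with all libraries and the block Cxcl9 and Cxcl10 kept their calls. Ccl5 differed by -7.47 ± 2.33 (adjusted p = 0.09, blocked adjusted p = 8.85e-05) and Cxcl11 by -2.82 (adjusted p = 0.81). Irgm1 (0.86 ± 0.15), the potassium channel subunit Kcns3 (2.79 ± 0.52) and Tnfaip8l3 (1.99 ± 0.24) differed in the other direction. Median differences were -3.00 for CXCR3 and CCR5 ligands (2 of 4 lower, 3 over the list alone, camera adjusted p = 4.32e-08) and -2.89 for MHC II (3 of 7, 5, 1.42e-06). They were -2.11 for antiviral genes (11 of 23, 16, 1.74e-12, adjusted p = 0.084 with an estimated correlation) and -1.06 for NF-kappaB targets (11 of 23, 14, 1.56e-13, adjusted p = 0.056 with an estimated correlation). They were -0.34 for MHC I (4 of 20, adjusted p = 3.60e-04, adjusted p = 0.63 with an estimated correlation) and -0.31 for receptors (6 of 16, 7, 2.02e-04, adjusted p = 0.18 with an estimated correlation). Immediate early genes had -0.53 (3 of 15, 6, 1.11e-04, adjusted p = 0.11 with an estimated correlation). Glycolysis genes had -0.25 (2 of 17, 0.0098, adjusted p = 0.83 with an estimated correlation, 0.21 without DSC replicate 2 and 0.24 without treated DSC replicate 1). The GTPase list did not pass (2 higher and 1 lower of 21, median -0.36, adjusted p = 0.48). The endothelial list had a median of 0.56 (adjusted p = 0.23, blocked, adjusted p = 5.31e-04). In total 700 genes passed edgeR. Of these, 150 had a larger and 550 a smaller log2 change in DSC, 236 by at least 2-fold. The blocked fit called 3190 (1179 larger and 2011 smaller), DESeq2 1075, the fit without the filter 439 and the fit of only the groups compared 238. Without treated MSC replicate 1, 463 were called.

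Against USC, the DSC response was smaller for Slfn2 (-5.33 ± 0.65), Fst (-4.62 ± 0.34), Mmp9 (-3.91), H2-Ab1 (-4.30 ± 0.49), Cx3cl1 (-2.67 ± 0.27), Nfkbia (-1.46), Nfkb2 (-0.95), H2-T23 (-1.18), Tapbpl (-1.29) and Zfp36 (-0.86). The apolipoprotein L gene Apol6 reached 225 from 21.9 CPM in DSC and 140 from 0.46 CPM in USC (-4.90 ± 0.22, adjusted p = 3.7e-09). The JAK inhibitor gene Socs1 reached 66.9 from 3.58 CPM in DSC and 80.5 from 18.6 CPM in USC (2.15 ± 0.22), and Igtp (1.33 ± 0.21) and Prickle2 (2.29 ± 0.29) also had larger log2 changes in DSC. The chemokines did not pass this test, with Cxcl9 at -1.42 (adjusted p = 0.57, and 0.043 without treated DSC replicate 1), Cxcl10 at -1.01 (adjusted p = 0.48) and Ccl5 at -6.27 ± 2.22 (adjusted p = 0.25). Blocked by replicate number, they passed (adjusted p = 0.0072, 5.47e-04 and 4.61e-04), and DESeq2 called Ccl5 (8.20e-06). The block also paired the USC cultures, which did not meet the pairing rule. Camera put MHC II (1 of 7 lower, 3 over the list alone, median -1.72, adjusted p = 4.87e-08) lower. NF-kappaB targets (6 of 23, 11 lower and 2 higher over the list alone, -0.55, 8.59e-09, adjusted p = 0.18 with an estimated correlation) and MHC I (3 of 20, 7 lower and 1 higher, -0.31, 5.09e-04, adjusted p = 0.67 with an estimated correlation) were lower too. It also put CXCR3 and CCR5 ligands lower (median -1.62, adjusted p = 2.36e-06, adjusted p = 0.11 with an estimated correlation), with none of 4 called by edgeR over all genes or over the list alone. In total 171 genes passed edgeR. Of these, 82 were larger and 89 smaller in DSC, 96 by at least 2-fold. The blocked fit called 1923, with the balance turned (1079 larger and 844 smaller), and DESeq2 454. The count was 272 without DSC replicate 1, 94, 108 and 113 without USC replicates 1, 2 and 3, and 108 and 98 without treated USC replicates 1 and 3.

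Some antiviral genes, 5 of the 23 listed, rose more in MSC than in USC. Rsad2, which encodes viperin, reached 434 ± 122 from 3.44 CPM in MSC and 50.6 from 4.35 CPM in USC (3.47 ± 0.53, adjusted p = 0.011). Oasl1 differed by 3.58 ± 0.60 (adjusted p = 0.014, 0.051 without USC replicate 3) and the ubiquitin-like modifier Isg15 by 2.71 ± 0.47 (adjusted p = 0.017, 0.092 and 0.059 without USC replicates 1 and 3). Igtp differed by 1.16 ± 0.19 and Apol6 by -2.03 ± 0.25. Gucy1b3, a guanylate cyclase subunit, differed by -1.62 ± 0.23 (7.8 from 47.7 CPM in MSC, 7.42 from 14.6 CPM in USC). Cxcl9 (1.76, adjusted p = 0.34) and Cxcl10 (1.63, adjusted p = 0.19) did not pass. They passed with the block (adjusted p = 2.45e-04 and 5.11e-06), with only the groups compared (0.029 and 0.0039) and with DESeq2 (0.041 and 0.019). Camera put the antiviral list higher in MSC (5 of 23 called, 15 over the list alone, median 1.42, adjusted p = 1.41e-14, adjusted p = 0.2 with an estimated correlation). The CXCR3 and CCR5 ligands were also higher (none of 4 by edgeR, 2 over the list alone, 1.41, 0.0025, adjusted p = 0.59 with an estimated correlation), as were NF-kappaB targets (none of 23, 4 over the list alone, 0.36, 1.40e-04, adjusted p = 0.77 with an estimated correlation). In total 112 genes passed edgeR. Of these, 98 were larger and 14 smaller in MSC, 53 by at least 2-fold. The blocked fit called 1726, DESeq2 266 and the fit of only the groups compared 235. The count was 50 and 73 without MSC replicates 2 and 3, 71 and 70 without treated MSC replicates 1 and 2, 44, 49 and 34 without USC replicates 1, 2 and 3, and 45, 64 and 43 without treated USC replicates 1, 2 and 3.

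Without cytokines at E7.5, DSC had more of the decidual gene Fst (301 ± 61 against 11.7 CPM, 4.68 ± 0.26, adjusted p = 3.1e-09) and the gap junction gene Gja1 (2470 ± 265 against 609 ± 73.6 CPM, 2.02 ± 0.13) than MSC. Gja1 lies on chromosome 10 from 56377330 to 56402513 on the plus strand. Pgr (0.42), Hoxa10 (1.56), Hoxa11 (1.59) and Wt1 (2.70) were higher in DSC. The ribonucleotide reductase gene Rrm2 (5.59 ± 0.53), the glucose transporter Slc2a1 (2.26), the TNF receptor Tnfrsf1b (3.15), Nfkbia (1.46), Zfp36 (2.37) and the Polycomb gene Cbx2 (1.62) were also higher in DSC. MSC had more of the smooth muscle myosin Myh11 (chromosome 16, 14194535 to 14291372, minus strand, 2.85 against 154 ± 18.8 CPM, -5.76 ± 0.17, adjusted p = 2.4e-12), Mylk (-4.62) and Acta2 (-1.27, adjusted p = 3.2e-03). Lower in DSC too were the matrix genes Loxl1 (-4.13), Tnc (-6.35) and Mfap4 (-8.95), prostacyclin synthase Ptgis (-7.22), the stromelysin Mmp3 (-7.33), the eosinophil chemokine Ccl11 (0.0718 against 131 ± 50.6 CPM, -10.75 ± 0.62) and the macrophage growth factor Csf1 (-4.15). Nmur2 and Six1 had 0 counts in DSC, at least 162-fold and 146-fold lower. Ifngr2 (-0.95), Irgm1 (-1.29) and Tap1 (-0.96) were lower in DSC, and Ezh2 did not pass (0.10, adjusted p = 0.45). Decidualization genes were higher in DSC (20 of 24 higher, 2 lower, median 1.95, camera adjusted p = 2.07e-07, adjusted p = 0.53 with an estimated correlation). So were glycolysis genes (15 of 17 higher, 1.36, 9.18e-06, adjusted p = 0.53 with an estimated correlation). Fibrillar matrix (23 of 27 lower, -1.79, 3.04e-08, adjusted p = 0.53 with an estimated correlation) was lower. GTPases (12 of 21 lower, -1.22, 0.0032, adjusted p = 0.53 with an estimated correlation) and MHC I (13 of 20 lower, -0.67, 0.0056, adjusted p = 0.54 with an estimated correlation) were lower, with pericyte markers (6 of 7 lower, -1.51, 0.0056, adjusted p = 0.53 with an estimated correlation). For NF-kappaB targets the median was 0.08 and the mean -0.18 (7 higher, 8 lower of 23, adjusted p = 0.72). Granzyme genes were in DSC libraries unevenly, with Gzmg (chromosome 14, 56156582 to 56159579, minus strand) at 21, 105 and 1.92 CPM in replicates 1 to 3 and 0 counts in MSC (at least 975-fold, adjusted p = 0.015). The NK and T cell list was higher by a median of 5.84 (6 of 7, adjusted p = 0.048, adjusted p = 0.54 with an estimated correlation). Its value was 0.081, 0.09 and 0.067 without DSC replicates 1 and 2 and MSC replicate 3. In total 8937 genes passed edgeR. Of these, 4357 were higher and 4580 lower in DSC, 3868 by at least 2-fold. The balance turned under RLE scaling (4544 and 4455) and with DESeq2 (4509 and 4384).

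Against USC, DSC had more of the tryptophan-degrading enzyme Tdo2 (403 ± 76.8 against 0.302 CPM, 10.50 ± 0.79, adjusted p = 4.9e-08), the Wnt inhibitor Sfrp5 (10.69) and the steroid hydroxylase Cyp11b1 (20.1 ± 8.88 CPM against 0 counts, at least 373-fold). Higher too were Angpt4 (5.53), Cxcl14 (5.78), Gja1 (3.31), Hoxa10 (2.18), Pgr (1190 against 610 CPM, 0.97 ± 0.09) and hexokinase Hk2 (3.23). Ldha (2.01), the mitotic genes Bub1 (5.17) and Aurkb (4.73), and keratin Krt19 (420 ± 142 against 2.28 CPM, 7.49) were also higher. Of the Polycomb genes, Jarid2 (169 against 23.4 CPM, 2.85 ± 0.22), Cbx2 (2.02) and Ezh2 (20.9 against 16.1 CPM, 0.37 ± 0.11, adjusted p = 7.0e-03) were higher. Lower in DSC were Myh11 (-6.42), Mylk (-4.18), Tnc (-5.93), Loxl1 (-4.12) and Ccl11 (-8.49). The gap junction gene Gjb2 (0.134 against 37.8 CPM, -8.27 ± 0.41), the kinase Prkcb (-7.78), Ptgis (-6.87), Csf1 (-4.38), Socs1 (-2.42), Igtp (-1.94) and Ciita (-1.93) were lower as well. Acta2 did not pass (-0.73, adjusted p = 0.058). Decidualization genes were higher (21 of 24, median 3.52, camera adjusted p = 7.55e-11, adjusted p = 0.4 with an estimated correlation). Cell cycle (23 of 25 higher, 2.84, 6.52e-10, adjusted p = 0.57 with an estimated correlation) and glycolysis genes (15 of 17 higher, 1.75, 1.80e-06, adjusted p = 0.73 with an estimated correlation) were higher. So were TGF-beta and YAP targets (10 of 18 higher, 3 lower, 0.59, 0.014, adjusted p = 0.63 with an estimated correlation). Pericyte markers were lower (6 of 7, -1.90, 0.0064, adjusted p = 0.57 with an estimated correlation). NF-kappaB targets had a median of -0.08 and a mean of 0.01 (adjusted p = 0.61). In total 9738 genes passed edgeR. Of these, 4446 were higher and 5292 lower in DSC, 4699 by at least 2-fold. The balance turned under RLE scaling (4911 and 4752) and with DESeq2 (4923 and 4610).

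Untreated MSC also differed from USC. The protease inhibitor A2m was at 571 ± 155 against 8.59 CPM (6.05 ± 0.59, adjusted p = 3.1e-06). Tdo2 was higher by 5.88, Angpt4 by 3.70 ± 0.25, Gja1 by 1.29, Pgr by 0.54 and the progesterone-degrading enzyme Akr1c18 by 3.12. The collagen Col12a1 (2.77 ± 0.20), the lysyl oxidase Loxl2 (1.98), the TGF-beta target Pmepa1 (2.74) and the myosin light chain Myl9 (1.68) were higher. So were Bub1 (4.71 ± 0.36), Aurkb (4.36), Ccl11 (2.26), Ccl12 (2.70), Ifit2 (2.25) and the Polycomb gene Ezh1 (0.63). The neuronal pentraxin Nptx1 (-2.98 ± 0.21), Rasgrf1 (-3.12), Gfra2 (-2.84), Crabp1 (-2.60), Egr1 (36.7 against 111 CPM, -1.59), Ier2 (-0.85) and Igtp (-0.72) were lower in MSC. Fibrillar matrix genes were higher in MSC (21 of 27, 22 over the list alone, median 1.70, camera adjusted p = 2.18e-10, adjusted p = 0.24 with an estimated correlation). So were cell cycle genes (21 of 25 higher, 1 lower, 2.48, 1.03e-09, adjusted p = 0.38 with an estimated correlation) and TGF-beta and YAP targets (12 of 18 higher, 1.15, 1.76e-04, adjusted p = 0.24 with an estimated correlation). Decidualization genes (16 of 24 higher, 1.30, 1.96e-04, adjusted p = 0.52 with an estimated correlation) and antiviral genes (13 of 23 higher, 0.76, 2.48e-04, adjusted p = 0.52 with an estimated correlation) were higher. Other chemokines were also higher (8 of 17, 1.05, 0.02, adjusted p = 0.38 with an estimated correlation). Immediate early genes were lower (12 of 15, -0.76, 1.04e-05, adjusted p = 0.24 with an estimated correlation). In total 7205 genes passed edgeR. Of these, 3650 were higher and 3555 lower in MSC, 2359 by at least 2-fold.

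Between E7.5 and E15.5, most decidualization genes fell in DSC. For the changes over the days in DSC and in MSC, any difference in preparation could not be told apart from the day itself. The thyroid hormone-inactivating gene Dio3 (chromosome 12, 110279068 to 110281097, plus strand) fell from 838 ± 107 to 0.245 CPM (-11.68 ± 0.64, adjusted p = 3.3e-07), Fst from 305 to 5.15 CPM (-5.89 ± 0.36) and Pgr from 1210 ± 122 to 203 ± 114 CPM (-2.57 ± 0.39, adjusted p = 2.7e-04). Lrat (-9.26), the convertase Pcsk5 (-9.22), Cxcl14 (-4.67), Hoxa10 (-2.54), Hoxd11 (-3.54) and Wt1 (-2.56) fell too. Of the 12 posterior Hox genes 4 were higher and 5 lower (median 0.43, camera adjusted p = 0.34). Rrm2 (-4.59), Synpo2 (-4.82), Col6a3 (445 from 1780 CPM), Pdk1 (-3.92) and the glycolytic enzyme Pfkl (-2.63) fell as well. Cxcl9 had 0 counts at E15.5, at least 13.4-fold below 0.477 CPM. Placental genes rose, with the prolactin relative Prl4a1 (chromosome 13, 28016212 to 28023559, plus strand) at 467 ± 248 CPM against 0 counts (at least 6730-fold), Tpbpb at 338 ± 164 CPM (11.20 ± 0.67) and Prl7a1 at 154 ± 76.9 CPM (11.55). Summed Y-linked genes were at 19.9, 133 and 62.3 CPM in E15.5 DSC replicates 1 to 3 and at no more than 0.451 CPM in the E7.5 DSC and the MSC libraries. E15.5 DSC replicate 2 stood apart from replicates 1 and 3, with a chi-square per gene of 163 and 164 where those 2 gave 9.41. Without it the number of genes called over the days was 11477. Sult1e1, which sulfates estrogen, went from 0 counts to 527 ± 296 CPM (at least 7580-fold), and the prostaglandin-degrading gene Hpgd rose by 7.03 ± 0.57. B2m (2.78 ± 0.22), Hmox1 (2.90), the macrophage marker Cd68 (3.82) and the endothelial gene Cdh5 (2.13) rose. Of the chromatin genes, Ezh2 (60 ± 5.67 against 20.2 ± 1.32 CPM, 1.57 ± 0.09, adjusted p = 4.6e-07), the H3K27 demethylase gene Kdm6b (chromosome 11, 69398508 to 69413675, minus strand, 132 ± 21.3 against 24.8 CPM, 2.41 ± 0.14) and Phf1 (2.43) rose. Decidualization genes fell (17 of 24, median -2.43, camera adjusted p = 3.05e-05, adjusted p = 0.81 with an estimated correlation). Cell cycle (12 of 25 lower, 2 higher, -1.23, 0.0081, adjusted p = 0.84 with an estimated correlation) and glycolysis (12 of 18 lower, 3 higher, -0.94, 0.012, adjusted p = 0.83 with an estimated correlation) fell. Trophoblast markers rose (14 of 15, 10.73, or 8.04 with bounds, 1.85e-07, adjusted p = 0.76 with an estimated correlation). Erythroid genes (6 of 6, 5.73, 0.0014, adjusted p = 0.81 with an estimated correlation) and immediate early genes (13 of 15, 1.44, 0.0014, adjusted p = 0.76 with an estimated correlation) rose. So did MHC I (12 of 20, 1.13, 0.014, adjusted p = 0.83 with an estimated correlation) and epithelial markers (9 of 12, 4.01, 0.016, adjusted p = 0.83 with an estimated correlation). The smooth muscle list (8 of 22 lower, 3 higher, -0.52) had an adjusted p of 0.046 (adjusted p = 0.83 with an estimated correlation). Its value was 0.054, 0.06, 0.15 and 0.1 without E7.5 DSC replicates 1 and 2 and E15.5 DSC replicates 1 and 3. In total 10128 of 17423 genes passed edgeR. Of these, 5351 were higher and 4777 lower at E15.5, 5633 by at least 2-fold. The balance turned under RLE scaling (5025 and 5076) and with DESeq2 (5040 and 5160).

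In MSC over the same days, the listed hypoxia and glycolysis genes and most listed NF-kappaB targets rose. Slc2a1 reached 483 ± 9.75 from 73.5 CPM (2.72 ± 0.24, adjusted p = 1.1e-05) and Egln3 149 ± 25.1 from 5.12 CPM (4.87). Cxcl1 reached 196 ± 21.1 from 3.11 CPM (5.98 ± 0.51) and the collagenase Mmp13 61.3 ± 18.8 from 2.63 CPM (4.56 ± 0.53). Tnfaip3 (2.46 ± 0.13), Sod2 (1.82), Rela (1.20), Cebpb (1.96), Junb (2.46 ± 0.13), Ier2 (2.94) and Ptges (2.43) rose. So did Tgfb1 (2.27), Kdm6b (2.70 ± 0.14), H2-Ab1 (4.34) and the hemoglobin gene Hbb-bs (chromosome 7, 103826534 to 103828096, minus strand, 221 ± 29.2 against 1.29 CPM, 7.48 ± 0.72). The small RNA gene Rpph1 (-8.26), Rrm2 (-3.19), Ccnb2 (-3.35), the antiviral genes Ifit2 (-2.17 ± 0.24) and Ddx58 (-1.78) and Ccl11 (-3.64) fell. So did the matrix genes Lum (-2.84) and Sparc (1050 from 2410 CPM, -1.20), Angpt4 (-3.03), Vcl (-1.12) and Cnn2 (-1.05). Rmrp had 0 counts at E15.5, at least 501-fold below 16.4 CPM. Pgr was at 627 against 924 CPM (-0.56, adjusted p = 0.23) and Ezh2 at 20 against 18.9 CPM (0.08 ± 0.09, adjusted p = 0.48). All 18 glycolysis genes rose (median 1.80, camera adjusted p = 1.10e-08, adjusted p = 0.47 with an estimated correlation). So did 14 of 15 immediate early genes (2.55, 1.10e-08, adjusted p = 0.084 with an estimated correlation) and 18 of 23 NF-kappaB targets (1.38, 7.93e-08, adjusted p = 0.084 with an estimated correlation). Of the erythroid genes 5 of 6 rose (8.36, or 7.67 with bounds, 5.73e-04, adjusted p = 0.62 with an estimated correlation), and of the epithelial markers 10 of 12 (4.72, 9.27e-04, adjusted p = 0.69 with an estimated correlation). Cell cycle genes fell (15 of 25 lower, 2 higher, -2.85, 5.73e-04, adjusted p = 0.86 with an estimated correlation). Fibrillar matrix (13 of 27 lower, -1.14, 0.0019, adjusted p = 0.69 with an estimated correlation) and antiviral genes (14 of 22 lower, 1 higher, -1.23, 0.015, adjusted p = 0.86 with an estimated correlation) fell. Trophoblast markers did not pass in MSC (0.34, adjusted p = 0.61). MHC I had a median of -0.12 and a mean of 0.30 (adjusted p = 0.94). In total 8679 genes passed edgeR. Of these, 4336 were higher and 4343 lower, 4279 by at least 2-fold, a near-even balance that turned in 5 of 6 fits without 1 library. DSC and MSC shared 2610 higher genes (1330 if independent) and 2504 lower genes (1190), while 345 and 383 changed in opposite directions. Here too both layers came from the same fit, so the counts under independence are no test of the overlap.

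**Figure D3:**
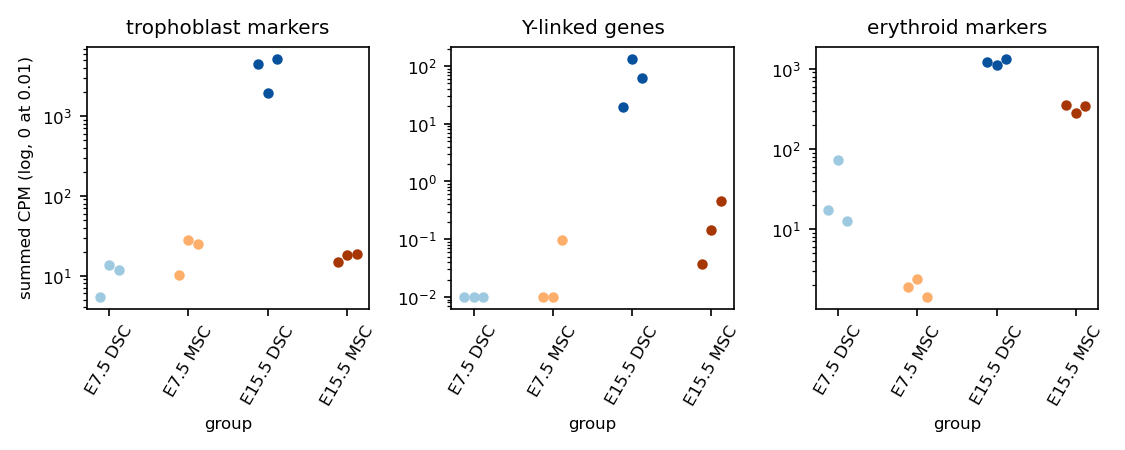
Summed CPM per library (points, log axis, libraries at 0 drawn at the foot) of trophoblast, Y-linked and erythroid genes in DSC and MSC at both days. The lowest Y-linked sum in E15.5 DSC was 19.9 CPM.

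The changes over time differed between layers. The phosphofructokinase gene Pfkl (chromosome 10, 77986947 to 78010083, minus strand) went from 247 to 39.9 CPM in DSC and from 98 to 345 CPM in MSC (difference -4.45 ± 0.25, adjusted p = 3.5e-06). Pdk1 went from 60.2 to 3.97 and from 30.3 to 107 CPM (-5.75 ± 0.36) and Fst from 305 to 5.15 and from 12 to 43.1 CPM (-7.73 ± 0.47). The pentraxin Ptx3 went from 19.2 to 0.692 and from 2.13 to 111 CPM (-10.47 ± 0.48). Fos went from 150 to 59.8 and from 19.8 to 119 CPM (-3.91). Tnfaip3 (-3.15), Nfkbia (-2.59), Junb (-2.12), Pgr (-2.02 ± 0.53, adjusted p = 0.016), Hoxd11 (-3.34) and Hoxa11 (-2.12) had the lower log2 change in DSC. So had Cxcl9 (-5.49), Cxcl10 (-2.20), H2-Ab1 (-4.60), Dio3 (-9.51) and Lrat (-10.99). Ezh2 (1.49 ± 0.13, adjusted p = 3.6e-05), Rbbp7 (1.43), which encodes a Polycomb-associated histone binder, B2m (2.35), H2-K1 (2.23) and Irf7 (2.88) had the higher one. So had Xaf1 (2.27), Hpgd (7.49), Cd68 (3.69), Prl7a1 (11.73), Plac1 (5.82) and Pappa2 (11.53). The proteoglycan Lum went from 15.1 to 421 CPM in DSC and from 633 to 88.3 CPM in MSC (7.66). Lists lower in DSC were glycolysis (16 of 18, 17 over the list alone, median -2.55, camera adjusted p = 5.71e-12, adjusted p = 0.24 with an estimated correlation) and NF-kappaB targets (14 of 23 lower, 1 higher, -1.11, 1.35e-05, adjusted p = 0.23 with an estimated correlation). Also lower were decidualization (11 of 24 lower, 1 higher, -1.48, 3.13e-04, adjusted p = 0.62 with an estimated correlation) and immediate early genes (8 of 15 lower, 2 higher, -1.09, 0.0077, adjusted p = 0.53 with an estimated correlation). Higher were trophoblast markers (8 of 15, 9 over the list alone, 7.77, 1.77e-10, adjusted p = 0.23 with an estimated correlation). So were MHC I (11 of 20, 1.15, 6.67e-04, adjusted p = 0.66 with an estimated correlation) and antiviral genes (13 of 22, 1.11, 0.0021, adjusted p = 0.73 with an estimated correlation). In total 5573 genes passed edgeR. Of these, 2871 had the higher and 2702 the lower log2 change in DSC, 3367 by at least 2-fold. The balance turned under RLE scaling (2778 and 2819), with DESeq2 (3085 and 3240) and in 6 of 12 fits without 1 library.

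At E15.5 itself, DSC exceeded MSC in placental genes (Prl7a1 11.09, Tpbpb 10.88), Sfrp5 (174 ± 95.7 against 0.183 CPM, 9.84), Rsad2 (4.22), Irf7 (3.63), H2-D1 (1280 against 333 CPM, 1.94) and Ctgf (3.01). Rrm2 (4.16), Cd68 (3.91), Kdr (2.64), Hmox1 (1.67), Rbbp7 (1.36) and Ezh2 (60 against 20 CPM, 1.58 ± 0.09, adjusted p = 1.5e-06) were also higher. Psg18 had 0 counts in MSC, at least 1550-fold below 50.9 ± 34.3 CPM. MSC exceeded DSC in Mmp3 (1960 ± 171 against 5.87 CPM, -8.38 ± 0.61), the opioid precursor Penk (-8.65), Steap4 (-9.10), Ngfr (-8.07), Myh11 (-4.57 ± 0.37) and Mylk (-3.81). Lower in DSC too were Col6a3 (3470 ± 345 against 445 CPM, -2.97), Pfkl (-3.11), Pdk1 (-4.75), Mmp13 (-6.21) and Pgr (627 against 203 ± 114 CPM, -1.63 ± 0.38, adjusted p = 5.6e-03). So were Cxcl10 (-1.87), Cxcl5 (-5.74), Ccl11 (-5.47), H2-Ab1 (-2.70) and Fst (-3.07). Trophoblast markers (15 of 15, median 10.15, camera adjusted p = 4.31e-10, adjusted p = 0.17 with an estimated correlation) and erythroid genes (6 of 6, 2.45, 0.0094, adjusted p = 0.51 with an estimated correlation) were higher in DSC. Lower were glycolysis (15 of 18, 16 over the list alone, 1.27e-06, adjusted p = 0.37 with an estimated correlation) and NF-kappaB targets (16 of 23 lower, 2 higher, -1.47, 9.48e-06, adjusted p = 0.17 with an estimated correlation). So were smooth muscle (13 of 22 lower, 2 higher, -1.91, 3.11e-04, adjusted p = 0.47 with an estimated correlation) and pericyte markers (5 of 8, -2.67, 0.007, adjusted p = 0.21 with an estimated correlation). Other chemokines (8 of 16 lower, 2 higher, -2.42, 0.007, adjusted p = 0.17 with an estimated correlation) and fibrillar matrix (12 of 27 lower, 5 higher, -1.16, 0.0094, adjusted p = 0.51 with an estimated correlation) were lower too. Cell cycle genes were higher (13 of 25, 1.65, adjusted p = 0.0078, adjusted p = 0.71 with an estimated correlation, 0.66 without E15.5 DSC replicate 2). In total 8014 genes passed edgeR. Of these, 4096 were higher and 3918 lower in DSC, 4430 by at least 2-fold, a balance that turned in 4 of 6 fits without 1 library. Without E15.5 DSC replicate 2 the count was 10326.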

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

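The tests of conceptus RNA, reads shared between family copies, library preparation, dividing cells, a uniformly weaker response and leukocytes were chosen only after the result was seen.

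The values in this part are differences between the effects in separate cell populations, drawn to attention because the difference itself passed its own test rather than because an effect was called in one population and not in the other. Of the cytokine responses, 700 genes differed between DSC and MSC, 171 between DSC and USC and 112 between MSC and USC by edgeR. Blocked by replicate number, the counts were 3190, 1923 and 1726, though the USC cultures did not meet the pairing rule. The fits without single libraries carry no block. The change from E7.5 to E15.5 differed between DSC and MSC for 5573 genes.

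Chemokine and interferon genes were among those that differed between the DSC and MSC responses, with Cxcl9 (-3.19), Cxcl10 (-2.64), Slfn2 (-4.55), Ifit1 (-3.55), Ifit2 (-3.07), Irf7 (-1.92), Gbp4 (-2.53) and Cx3cl1 (-2.01) lower in DSC. The matrix-degrading genes Mmp9 (-4.39) and Mmp13 (-4.36), the activin antagonist Fst (-4.48), the class II genes H2-Ab1 (-3.49) and Ciita (-4.48) and the class I gene H2-T23 (-1.20) were lower too. So were the NF-kappaB feedback genes Nfkbia (-1.66) and Tnfaip3 (-2.01), Zfp36 (-1.38), Junb (-1.13), Slc2a1 (-1.46) and Traf2 (-0.69). Irgm1 (0.86), Nppc (3.01) and Kcns3 (2.79) were higher in DSC. Lower and higher here refer to the log2 response, not to the treated level. Fst, Slfn2, Nfkbia, Zfp36 and Slc2a1 already stood higher in untreated DSC than in untreated MSC. Without single libraries, Cxcl9 had an adjusted p of 0.058 to 0.18 for all but treated DSC replicates 1 and 2 and treated MSC replicate 3. Mmp13 had an adjusted p of 0.056 to 0.1 (DSC replicates 1, 2 and 3), Nppc 0.053 and 0.09 (DSC replicate 2 and treated DSC replicate 1) and Ciita 0.066 and 0.11 (DSC replicates 2 and 3). List medians were -3.00 for CXCR3 and CCR5 ligands, -2.11 for antiviral genes, -0.34 for MHC I, -2.89 for MHC II, -1.06 for NF-kappaB targets, -0.31 for receptors, -0.25 for glycolysis and -0.53 for immediate early genes. With an estimated correlation the CXCR3 and CCR5 ligands (0.047) and MHC II (0.018) kept the call, while antiviral genes (0.084), MHC I (0.63), NF-kappaB targets (0.056), receptors (0.18), glycolysis (0.83) and immediate early genes (0.11) lost it.

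Between the DSC and USC responses, Slfn2 (-5.33), Apol6 (-4.90), Fst (-4.62), Mmp9 (-3.91), H2-Ab1 (-4.30), Nfkbia (-1.46) and Cx3cl1 (-2.67) were lower in DSC. Igtp (1.33), Socs1 (2.15), Prickle2 (2.29), the haptoglobin gene Hp (2.56, adjusted p = 0.033) and Angpt4 (2.20) were higher. These too are log2 responses, not treated levels. Treated Apol6 was higher in DSC than in USC, and untreated Igtp and Socs1 were lower in DSC. Angpt4 had an adjusted p of 0.082 and 0.058 without treated USC replicates 1 and 3. Hp had 0.074 without DSC replicate 3, 0.057 without treated DSC replicate 3, 0.21 and 0.15 without USC replicates 1 and 2 and 0.092 and 0.088 without treated USC replicates 1 and 3. List medians were -1.62 for CXCR3 and CCR5 ligands, -0.31 for MHC I, -1.72 for MHC II, -0.55 for NF-kappaB targets, -0.17 for receptors, 0.41 for fibrillar matrix and -0.18 for immediate early genes. With an estimated correlation MHC II (0.0064) alone of these kept the call, while CXCR3 and CCR5 ligands (0.11), MHC I (0.67), NF-kappaB targets (0.18), receptors (0.67), matrix (0.67) and immediate early genes (0.41) lost it. The last 3 lists were called by camera with adjusted p-values of 0.021, 0.0026 and 0.0046. Left out singly, DSC replicate 2, treated DSC replicate 1 and treated USC replicate 2 gave 0.11, 0.066 and 0.056 for receptors. DSC replicate 3, treated DSC replicate 1 and treated USC replicate 1 gave 0.084, 0.086 and 0.05 for matrix, and DSC replicate 3 gave 0.084 for immediate early genes.

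Between the MSC and USC responses, the antiviral genes Oasl1 (3.58), Rsad2 (3.47), Oas2 (2.94), Ifit1 (2.74) and Isg15 (2.71), together with Ccl12 (2.12), Igtp (1.16), Socs1 (1.11) and the vasodilator gene Adm (1.64), were higher in MSC. Apol6 (-2.03) and Gucy1b3 (-1.62) had the lower log2 response in MSC. Several calls ended without single libraries. Ifit1 (adjusted p of 0.052 to 0.17) and Oas2 (0.052 to 0.2) lost theirs without each of MSC replicates 1 to 3, treated MSC replicates 1 and 2, USC replicates 1 to 3 and treated USC replicates 1 to 3. Ccl12 (0.051 to 0.27) lost it without the same libraries except MSC replicate 1. Adm (0.052 to 0.068) lost it without MSC replicates 1 and 2, treated MSC replicate 2, USC replicates 1 and 3 and treated USC replicates 1 to 3. Socs1 (0.05 to 0.056) lost it without MSC replicate 2, USC replicates 1 and 3 and treated USC replicate 1, Isg15 (0.092 and 0.059) without USC replicates 1 and 3 and Oasl1 (0.051) without USC replicate 3. List medians were 1.41 for CXCR3 and CCR5 ligands, 1.42 for antiviral genes, 0.36 for NF-kappaB targets, 0.19 for receptors, 0.39 for fibrillar matrix and 0.24 for glycolysis. No list of these kept the call with an estimated correlation (0.59, 0.2, 0.77, 0.91, 1 and 1, in this order). The last 3 lists had adjusted p-values of 0.044, 0.037 and 0.014. Without single libraries, matrix had 0.12, 0.1, 0.082 and 0.36 (MSC replicate 3, treated MSC replicate 1, USC replicate 2, treated USC replicate 1) and glycolysis 0.11, 0.053 and 0.065 (MSC replicate 1, treated MSC replicate 3, treated USC replicate 1).

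Over the days, single glycolysis and NF-kappaB genes were among those that differed between the layers. Pfkl (-4.45), Pdk1 (-5.75), Fst (-7.73), Dio3 (-9.51), Tnfaip3 (-3.15), Nfkbia (-2.59), Pgr (-2.02), Hoxd11 (-3.34), Hoxa11 (-2.12), Cxcl9 (-5.49), Ptx3 (-10.47), Junb (-2.12), Fos (-3.91) and H2-Ab1 (-4.60) had the lower change in DSC. Ezh2 (1.49), Rbbp7 (1.43), B2m (2.35), H2-K1 (2.23), Irf7 (2.88), Lum (7.66), Hpgd (7.49), Plac1 (5.82), Prl7a1 (11.73) and Cd68 (3.69) had the higher one. List medians were 1.11 for antiviral genes, 1.15 for MHC I, -1.11 for NF-kappaB targets, -1.48 for decidualization, -2.55 for glycolysis, -1.09 for immediate early genes and 7.77 for trophoblast markers. No list of these kept its call with an estimated correlation (0.73, 0.66, 0.23, 0.62, 0.24, 0.53 and 0.23, in this order).

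Placental and Y-linked transcripts appeared together in E15.5 DSC. The lowest summed level of Y-linked genes there was 19.9 CPM, against at most 0.451 CPM in the 9 other DSC and MSC libraries of the table with both days, which is consistent with RNA of male conceptuses in those preparations. Of 4 tested placental genes outside the prolactin, Psg, Tpbp and cathepsin families, 3 were also higher, which reads shared within those families cannot explain. For the family members themselves, shared reads stay open, since genes outside the families cannot test this. Trophoblast sums were 4470, 1930 and 5210 CPM and Y-linked sums 19.9, 133 and 62.3 CPM in replicates 1 to 3, so the lowest trophoblast sum went with the highest Y-linked sum. Erythroid sums were 1200, 1120 and 1330 CPM there but also 351, 279 and 339 CPM in E15.5 MSC, where Y-linked sums stayed under 0.5 CPM, so red cell RNA did not follow the Y-linked signal. Whether any given gene that rose in E15.5 DSC, such as Ezh2, Cd68 or Hpgd, came from stroma or from these cells stays open. For genes that fell, or that differed between the layers over the days, a changed cell mix in E15.5 DSC was not tested either.

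Small non-coding RNAs and histone mRNAs, which lack long poly(A) tails, were lower at E15.5 in both layers. Of 152 tested small non-coding RNAs, 87 were lower in both DSC and MSC, and their median was -2.95 in MSC beside -2.85 for the cell cycle list, but -2.53 in DSC beside -1.23. Of 56 histone genes, 47 were lower in both layers, with medians of -5.92 in MSC and -4.23 in DSC. A different library preparation on the later day or fewer dividing cells could each give this. In DSC the median of the small non-coding RNAs fell more than that of the cell cycle list, a difference that was not tested. In MSC the quartiles of these 2 sets overlapped (-5.9 to -0.31 and -4.52 to -0.55). The labels give no preparation dates, so whether preparation differed between the days is unknown and the tables leave both open. Whether such a difference also moved other genes compared over the days was not tested.

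The response of the CXCR3 and CCR5 ligands as a list was smaller in DSC than in MSC. Singly, edgeR without the block called Cxcl9 and Cxcl10 and did not call Ccl5 and Cxcl11, and the list of other chemokines was not called. Ccl5 did pass with the block by replicate number, and DESeq2 called it too. The values argue against a uniformly weaker response, with the same log2 difference in every list. The GTPase list had a median difference of -0.36 (quartiles -0.7 to 0.39, n = 21). The CXCR3 and CCR5 ligands had -3.00 (quartiles -4.26 to -2.78, n = 4). A broad weakening that spared the GTPases, whose untreated levels were lower in DSC as a list, is not excluded. More leukocytes in the MSC cultures stays open, though most of the 9 myeloid markers ran against it. Csf1r (26.4 against 23.8 CPM) and Lyz2 (1.04 against 0.655 CPM) were the 2 higher in treated MSC than in treated DSC. The others were lower, among them Ptprc (0.104 against 2.62 CPM), Fcer1g (3.23 against 12.5 CPM), Laptm5 (0.356 against 2.96 CPM) and Cd68 (14.8 against 20.1 CPM). A repressive histone mark on these promoters is a hypothesis that might fit, and H3K27me3 was not measured here. Chromatin immunoprecipitation at Cxcl9, Ccl5 and Ciita in the same cultures would test it.

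Regrouping the libraries of a comparison of 3 against 3 gives 10 splits, too few for a share under 0.05, and the true grouping was the only 1 of 10 to reach its own count. The real count and the highest of the other splits were 1343 and 83 for cytokines in DSC, 4761 and 1 in MSC and 2655 and 0 in USC. They were 8937 and 0 for untreated DSC against MSC, 9738 and 1 for DSC against USC and 7205 and 0 for MSC against USC. They were 10128 and 2 for the days in DSC, 8679 and 0 in MSC and 8014 and 0 for the layers at E15.5. All other splits of 3 against 3 mixed libraries of the compared groups, which widens the spread within groups. Their low counts therefore carry no information on chance. For the differences between responses, 13 of 100 drawn splits each reached 700 (highest 10193), 171 (11730) and 112 (9730), and for the day difference 2 of 100 reached 5573 (highest 8826). The splits with many genes swapped layer labels within an arm, so they point to the structure of the samples and this test settles chance for none of these 4 differences. Among the 41 splits with equal layer numbers in both arms, the highest other count was 0. Each group of these other splits mixed the layers, which widens the spread within groups, so that 0 carries no information on chance.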

How the results depend on the processing

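The settings without poly(A)-lacking genes, without genes low outside E15.5 DSC, with thinned counts and without E15.5 DSC replicate 2 and E7.5 MSC replicate 3 together are tests chosen only after the result was seen; the other settings were fixed before.

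A value changed sign only for Ezh2 under cytokines in USC, from -0.05 to 0.02 without USC replicate 1 and to 0.02 without treated USC replicate 2, neither with a call. The other values without 1 library lay between -0.09 and -0.06. The cause was not tested. RLE scaling moved the median log2 fold changes by at most 0.06. It moved the share of higher genes among the USC calls from 45.6% to 53.4%. The balance of higher and lower calls turned in DSC with the block, from 62.2% to 41.9% higher, and was 84.7% (569 and 103) in the groups alone and 75.5% (827 and 269) without the filter. It turned in MSC with the block (51.6% to 47.4%) and in USC without the filter (56.8%), with DESeq2 (51.9%) and in the groups alone (50.7%). With the block it moved from 21.4% to 37% for DSC minus MSC and from 87.5% to 74.2% for MSC minus USC, and turned for DSC minus USC (48% to 56.1%) and the E15.5 layers (51.1% to 49.9%). With RLE and with DESeq2 it turned for untreated DSC against MSC (48.8% to 50.5% and 50.7%), untreated DSC against USC (45.7% to 50.8% and 51.6%), the days in DSC (52.8% to 49.7% and 49.4%) and the day difference (51.5% to 49.6% and 48.8%). With 1 library left out it turned in USC (52.2% to 52.8%), DSC minus USC (50.4% to 54.7%), the day difference (47.1% to 49.8%), the days in MSC (3872 higher and 3853 lower without E7.5 MSC replicate 1, 3903 and 3643 without replicate 3, and 3893 and 3731, 3787 and 3586, and 3845 and 3631 without E15.5 MSC replicates 1, 2 and 3) and the E15.5 layers. For these it was 5021 and 5305 without E15.5 DSC replicate 2 and 3349 and 3373, 3356 and 3361, and 3303 and 3306 without E15.5 MSC replicates 1, 2 and 3. Without the filter the days in MSC had 4390 and 4384. Among the settings added later it turned for the days in MSC without poly(A)-lacking genes (4287 and 4245) and with thinned counts (3447 and 3315), for the day difference with thinned counts (1949 and 2055) and without the 2 libraries (3500 and 3725), and for the E15.5 layers without the 2 libraries (4966 and 5108).

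Counts moved more than 1.5-fold in these cases, and the cause was not tested. Fitting only the groups compared gave 672 for DSC, 4146 for USC, 238 for DSC minus MSC and 235 for MSC minus USC. The block gave 3808 for DSC, 7827 for MSC, 5562 for USC, 3190 for DSC minus MSC, 1923 for DSC minus USC and 1726 for MSC minus USC. USC and the layers did not meet the pairing rule (correlations of 0.09 to 0.16 for USC), so their blocked counts rest on replicate numbers alone. DESeq2 gave 1075 for DSC minus MSC, 454 for DSC minus USC and 266 for MSC minus USC, and no filter gave 439 for DSC minus MSC. Camera called 110 of 334 lists, 24 with an estimated correlation, 107 with RLE, 137 without the filter, 118 with the block and 105 to 116 with a library left out.

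With 1 library left out, counts ran from 1069 to 1207 for DSC, 3790 to 4245 for MSC, 1784 to 2282 for USC and 463 to 884 for DSC minus MSC, the lowest without treated MSC replicate 1. They ran from 94 to 272 for DSC minus USC, moved without DSC replicate 1 (272), USC replicates 1 (94), 2 (108) and 3 (113) and treated USC replicates 1 (108) and 3 (98). For MSC minus USC they ran from 34 to 151, moved without MSC replicates 2 (50) and 3 (73), treated MSC replicates 1 (71) and 2 (70), USC replicates 1 (44), 2 (49) and 3 (34) and treated USC replicates 1 (45), 2 (64) and 3 (43). The untreated counts ran from 8015 to 8663 for DSC against MSC, 8831 to 9694 for DSC against USC and 5777 to 6402 for MSC against USC. Those of the days ran from 9092 to 11477 in DSC, 7373 to 7725 in MSC and 4358 to 7886 for the difference, and those of the E15.5 layers from 6609 to 10326. The highest of the DSC, difference and E15.5 counts came without E15.5 DSC replicate 2.

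The block gained Cxcl9 (-1.56, adjusted p = 0.0072), Cxcl10 (-1.09, 5.47e-04) and Ccl5 (4.61e-04) for DSC minus USC and Cxcl9 (1.71, 2.45e-04), Cxcl10 (1.60, 5.11e-06) and Ciita (2.75, 0.0011) for MSC minus USC. It lost Cxcl9 for the days in MSC (0.054), Gypa for the day difference (0.071), Acta2 for the E15.5 layers (0.077), receptors for MSC minus USC (0.068), parturition (0.065) and cell cycle (0.055) for untreated DSC against MSC and parturition at E15.5 (0.054). With those given beside the paired results, it changed no other call of a named gene. Cxcl9 for DSC minus MSC lost its call without the filter (0.18) and in the groups alone (0.1), and Cxcl10 in the groups alone (0.058). In the groups alone calls also ended for Mmp13 (0.08), Nppc (0.099) and Ciita (0.067) for DSC minus MSC, Hp for DSC minus USC (0.056) and Fos in DSC (0.099). Without the filter they ended for Mmp13 (0.079), Nppc (0.051), Angpt4 for DSC minus USC (0.05), Oas2 (0.052), Ifit1 (0.14) and Adm (0.09) for MSC minus USC, Gzmg for untreated DSC against MSC (0.068) and Psg18 at E15.5 (0.062). DESeq2 called Ccl5 (0.038), Cd74 (0.025) and Ciita (0.049) in DSC, Ccl5 for DSC minus USC (8.20e-06) and, with a small p, for DSC minus MSC, and Cxcl9 (0.041), Cxcl10 (0.019) and Ciita (0.0086) for MSC minus USC. Only the groups compared called Cxcl9 (0.029) and Cxcl10 (0.0039) for MSC minus USC. Pgr for the days in MSC gained one in the groups alone (2.98e-04).

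After the data were seen, leaving out poly(A)-lacking genes gave 9991, 8532, 5565 and 7978 calls for the days in DSC, in MSC, their difference and the E15.5 layers. Leaving out genes under 1 CPM outside E15.5 DSC gave 9192, 5109 and 7137 for DSC, the difference and the E15.5 layers. Thinning all libraries to 10675516 counts gave 8259, 6762, 4004 and 6105. This was the effect of depth on the number of calls, which fell in each of these comparisons. Leaving out the 2 libraries together gave 11249, 9785, 7225 and 10074.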

Other observations

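None of the tests in this part were chosen only after the result was seen.

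Polycomb genes did not move as a list in any comparison, though single members did. Under cytokines Cbx2 fell in DSC (-0.87 ± 0.14) while Mtf2 rose (0.44), and Aebp2 rose in MSC (1.09 ± 0.11) and USC (0.82). The list had 2 genes higher and 3 lower of 22 in DSC (median -0.12, camera adjusted p = 0.27), 2 higher and 8 lower in MSC (-0.17, adjusted p = 0.14) and 2 higher and 6 lower in USC (-0.09, adjusted p = 0.32). From E7.5 to E15.5 it had 9 higher and 6 lower in DSC (0.23, adjusted p = 0.35) and 7 higher and 4 lower in MSC, with a median of -0.16 and a mean of 0.23 (adjusted p = 0.62). Posterior Hox genes, which pattern the uterus, had 4 higher and 5 lower of 12 over the days in DSC (median 0.43, camera direction lower, adjusted p = 0.34) and 1 higher and 2 lower in MSC (median 0.13, camera direction lower, adjusted p = 0.88).

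The 7 marker lists given here did not pass under cytokines in DSC, though the endothelial list (median -0.61, adjusted p = 0.29) passed as lower when blocked by replicate (0.0013). The other medians were 0.03 for myeloid cells (none of 9 called by edgeR, camera adjusted p = 0.81), -0.01 for NK and T cells (0.91), 0.00 for epithelium (0.81), 0.46 for trophoblast (0.29), -0.32 for mesothelium (0.38) and 0.10 for erythroid genes (0.7). In MSC the endothelial list was lower (2 of 11 called, median -0.98, adjusted p = 0.045, adjusted p = 0.74 with an estimated correlation). It had 0.28, 0.16 and 0.14 without MSC replicate 1 and treated MSC replicates 2 and 3. TGF-beta and YAP targets did not pass in DSC (0.10, adjusted p = 0.56) or MSC (0.41, adjusted p = 0.25), and neither did parturition genes (0.15, adjusted p = 0.29, and 0.08, adjusted p = 0.18) or smooth muscle genes (-0.12, adjusted p = 0.71, and -0.15, adjusted p = 0.61).

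Untreated DSC differed from MSC in more lists whose calls depended on single libraries. Parturition genes were lower (12 of 19, median -1.48, adjusted p = 0.048, and 0.054, 0.065 and 0.082 without DSC replicates 1 and 2 and MSC replicate 3). Cell cycle genes were higher (8 of 25, 0.33, adjusted p = 0.048, and 0.37, 0.051 and 0.067 without DSC replicate 1 and MSC replicates 2 and 3). Erythroid genes were higher (5 of 5, 5.26, or 4.51 with bounds, adjusted p = 0.048, and 0.054, 0.065 and 0.067 without DSC replicates 1 and 2 and MSC replicate 3), and so were immediate early genes (7 of 15, 0.49, adjusted p = 0.021). With an estimated correlation these 4 lists had 0.53, 0.69, 0.54 and 0.53. At E15.5, antiviral genes were higher in DSC (12 of 22, 1.07, adjusted p = 0.026, and 0.066 without E15.5 DSC replicate 1), GTPases lower (9 of 19, -0.66, adjusted p = 0.042, and 0.37 and 0.054 without E15.5 DSC replicate 2 and E15.5 MSC replicate 1) and parturition genes lower (9 of 21, -1.14, adjusted p = 0.045, and 0.054, 0.054 and 0.052 without E15.5 DSC replicate 3 and E15.5 MSC replicates 1 and 2). With an estimated correlation these had 0.71, 0.68 and 0.3.

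Cytotoxic lymphocyte genes varied among the E7.5 DSC replicates. Gzmf was at 21.4, 94.1 and 1.68 CPM, Gzmd at 20.8, 81.4 and 1.5 CPM, the perforin gene Prf1 at 8.71, 38.4 and 0.722 CPM and the leukocyte gene Ptprc at 1.03, 5.11 and 0.421 CPM in replicates 1 to 3. For Ptprc the DSC against MSC difference of 5.14 had an adjusted p of 4.7e-03, and of 0.066 without DSC replicate 2.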
